A study of Paeonia lactiflora with 8 samples.

How the data were processed

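RNA was measured in root, leaf and flower of herbaceous peony collected at the blossom period and in fruit collected at the young fruit period, with 2 biological replicates per tissue and 8 libraries in all. Per the labels' protocols, poly(A) RNA was selected from total RNA, fragmented and reverse-transcribed, and paired-end libraries were read on an Illumina HiSeq 2000. One table covers all libraries. Per the file headers, it holds the authors' estimated counts per assembled gene, their TPM and their RPKM, with gene length and effective length. The deposited estimated counts are mostly whole numbers (97.98% or more of each library's values within 0.005 of a whole number) and are not normalised. The deposited TPM sum to the same total in each library, and the deposited RPKM are proportional to the TPM within each library and were not used further. The IDs are components of a de novo assembly. The assembler, the aligner, the counting tool, their settings and any filter are not given in the sources used here, and no genome was used, so that genes have no coordinates. Reads shared between near-identical assembled genes, such as paralogs, may be split between IDs by the counting, and single members of large families are uncertain in this respect. The labels do not say whether the libraries keep strand, and antisense transcripts were not separated.

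Of 30177 IDs, 13595 have a gene symbol in the table, 7134 a KEGG description and 12497 GO terms, and 15593 have neither symbol nor description. Gene names, descriptions and GO terms were taken from the table alone. Symbols come from other plants, and several IDs can share one. Columns were matched to samples by their names, tissues were taken from the labels, and every column of values matched a library. No pair of libraries had identical counts. The total count per library ranged from 30399492 to 49421130. Shares of a single library's counts are given with Wilson 95% intervals, and a group at 0 allows up to 3 counts over its libraries.

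The counts were rounded to whole numbers and tested with edgeR's quasi-likelihood test (edgeR 4.0.16 and limma 3.58.1 in R 4.3.3), with TMM scaling, the filterByExpr filter by tissue, and one fit over all 8 libraries with tissue as the only term. The filter kept 27939 genes and removed 2238. The fit had 4 residual degrees of freedom, a common biological coefficient of variation of 0.667 and a median prior of 2.88 degrees of freedom, and TMM factors ran from 0.581 (flower replicate 2) to 1.43 (root replicate 2). A gene passed with a two-sided Benjamini-Hochberg adjusted p under 0.05 over all genes tested and an absolute log2 fold change of at least 1. The 3 main comparisons set root against leaf, flower and fruit, and the 3 secondary ones set the other tissues against each other. A tissue-enriched gene passed the contrast of its tissue with the mean of the other 3 at an adjusted p under 0.05 and lay at least 1 log2 unit above each other tissue. Comparisons that share a tissue share its libraries, and no overlap between comparisons is reported. Standard errors were derived from the F statistic and the log2 fold change. Log2 CPM for correlations and principal components used a prior count of 2. Fruit was collected at another period than the other tissues, so tissue and period cannot be told apart in comparisons with fruit.

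Gene lists were defined by words and KEGG numbers matched to the table's annotation. Before the data were examined, 27 lists, the tests, the rule for named genes and most alternatives were fixed; 2 of these lists had no member and 1 had too few for a set test. A further 9 lists were built from symbols and GO terms after the annotation and before the tests were seen, and they were adjusted apart from the fixed ones. Those discussed with named genes are terpene synthases by gene product, seed storage, fermentation, and root transport and peroxidases. The wider lists of auxin response and microRNA target factors by symbol and of pollen genes by GO term are given beside their fixed counterparts. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the lists of a comparison. The lists were limited by the annotation's words. The fixed microRNA target list held TCP genes, the fixed pollen list held SF3 genes, and the fixed terpene synthase list held mostly trehalose genes.

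Named genes were chosen as follows. Part (a) takes, for each discussed list in a main comparison, up to 2 higher and up to 2 lower genes with the highest mean over the 8 libraries among those that passed; which lists are discussed was chosen after the test results were seen. Part (b) takes the 5 higher and 5 lower genes with the largest absolute log2 fold change among those that passed with a mean of at least 10 CPM in the higher tissue, no overlap between the libraries of the tissues and an informative annotation, here a KEGG description or a symbol that is not a locus code. Part (c) takes, for each enzyme of the MEP, MVA and prenyltransferase lists, the ID with the highest mean, whether or not it passed. Part (d) takes the 3 IDs of the fixed terpene synthase list with the highest mean. Part (e) takes 3 genes per direction by the filters of (b) for secondary comparisons and tissue-enriched genes. Not every gene selected by the rule is given, and counts of named genes include those left out. Genes outside this rule are said to have been named after their values were seen.

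The steps were tested on simulated data. For root against leaf, 200 of 27194 genes were changed in counts drawn with the fitted spread, and 0% of those changed 2-fold, 4.48% of those changed 4-fold and 33.3% of those changed 8-fold passed, with 0% false among 25 calls by edgeR. With a coefficient of variation of 0.2 and 27191 genes, the same comparison recovered 50.7%, 98.5% and 100% at 2-fold, 4-fold and 8-fold, with 5.68% false among 176 calls. For leaf against fruit, where no gene was changed, edgeR made 0 calls at either spread. For root against leaf at the fitted spread, camera gave a list of 40 raised genes p = 2.68e-41 and a list of 40 unchanged genes p = 0.956 at the preset correlation, and p = 9.16e-05 and 0.953 with an estimated correlation. The simulated genes were drawn independently, so these p-values do not test camera on lists whose genes are correlated. The search for transcripts that follow the replicate number found 50 of 50 planted IDs among 27939 genes and 0 under the other assignments of the numbers. The planted IDs were abundant and wholly absent from the libraries of one replicate number, so recovery of IDs at low levels was not tested.

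The alternatives planned before the data were examined were DESeq2 size factors, no filter on counts, the DESeq2 Wald test (DESeq2 1.42.0), limma-trend on log2(CPM + 1), only the 4 libraries compared, the replicate number as a block, each library left out in turn, no fold threshold, edgeR's glmTreat against a log2 fold change of 1, total scaling without the 20 highest genes, 1 ID per description in the lists, the other set tests, and, for the TPM, a pseudocount of 0.1, a laxer and a stricter filter, quantile and median-ratio scaling, and limma without trend and robust fitting. The alternatives added after the data were seen were limma-trend on log2(TPM + 1), the fit without the TAR1-A IDs, the block with the fruit numbers crossed, and the block in camera. Tables were handled in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. Small RNA and degradome data of the study were not used here.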

Results

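Poly(A) RNA was measured by paired-end sequencing in root, leaf, flower and fruit of herbaceous peony, with 2 biological replicates of each tissue and 8 libraries in all. Root, leaf and flower came from the blossom period and fruit from the young fruit period, so tissue and period were confounded for fruit. The estimated counts summed to 44392652 and 40901054 in root replicates 1 and 2, 49173429 and 42795795 in leaf, 39758080 and 30399492 in flower, and 49421130 and 39919793 in fruit. Of 30177 assembled genes, 27939 were tested and 2238 were removed by the filter on counts by tissue, 70 of them with at least 1000 counts in a single library. Replicates of one tissue correlated across genes at 0.874 (root), 0.909 (leaf), 0.884 (flower) and 0.914 (fruit), Pearson's r of log2 CPM, and genes are not independent replicates. IDs named TAR1-A, a name given to transcripts antisense to ribosomal RNA, took 41.4% of the counts of flower replicate 2 (Wilson 95% interval 41.39% to 41.43%) and 1.77% of those of leaf replicate 2 (1.765% to 1.773%). In root, leaf and flower, 137 IDs were present in replicate 1 and at no more than 2% of that level in replicate 2, and 113 had the reverse pattern. Of the counts of fruit replicate 2, 29.6% (Wilson 95% interval 29.54% to 29.57%) came from 75 IDs, including seed storage genes, that took 0.101% (0.0999% to 0.102%) in fruit replicate 1. A pair of values after an ID is the log2 fold change ± SE (n = 2 per tissue), levels are mean CPM ± SD (n = 2), and a fold given as "at least" is set against 3 counts over the tissue at 0. List medians marked "at bound" have such genes at that bound. Adjusted p is Benjamini-Hochberg over all genes tested with edgeR, and for gene lists over the lists of a comparison. Intervals and floors cover counting error only, and p-values measure the spread between these samples.

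**Figure D1:**
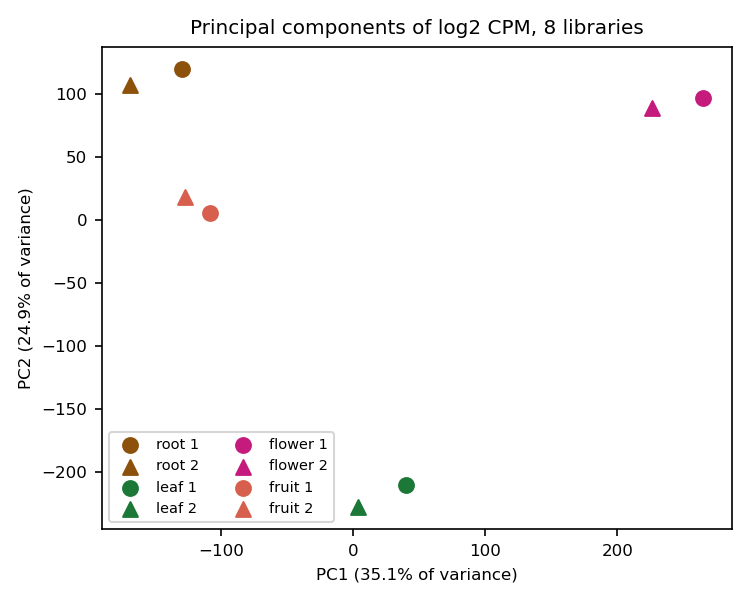
Each point is 1 library on the first 2 principal components of log2 CPM (x axis 35.1% and y axis 24.9% of the variance), coloured by tissue with circles for replicate 1 and triangles for replicate 2. Libraries of leaf and of flower lie apart from those of root and fruit.

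**Figure D2:**
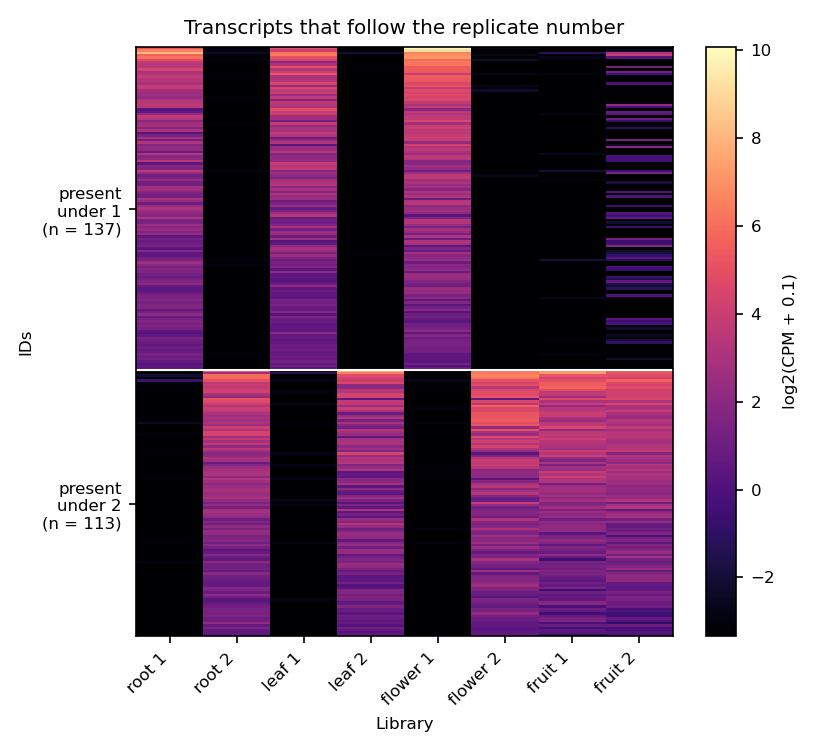
Colour gives log2(CPM + 0.1) in the 8 libraries (x axis) of the 137 IDs present in root, leaf and flower replicate 1 and at no more than 2% of that level in replicate 2, and of the 113 IDs with the reverse pattern (y axis). Of these 250 IDs, 98.8% were in the state of number 2 in fruit replicate 1.

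Root against leaf addressed which genes separate the underground organ, where paeoniflorin has its medicinal source, from the photosynthetic organ. Most photosynthesis genes were lower in root, and some cytosolic isoprenoid, fermentation and heat shock genes were higher. In the photosynthesis list, 55 of 69 genes tested were lower in root and 14 did not pass (60 lower adjusted over the list alone). The list had a median log2 fold change of -9.59. CAB-151 (comp23126_c0, -10.06 ± 1.84), a chlorophyll-binding antenna protein, reached 32548 ± 14429 CPM in leaf and 30.4 ± 38.0 in root. RBCS (comp23363_c0, -13.64 ± 1.40), the small subunit of the carbon-fixing enzyme Rubisco, reached 31493 ± 120.1 CPM in leaf and 2.47 ± 1.37 in root. In the mevalonate (MVA) list, which supplies cytosolic isoprenoids, 5 of 16 genes tested were higher in root and 11 did not pass (6 higher and 1 lower adjusted over the list alone). The list had a median log2 fold change of 1.07. Besides those given here with values, the higher ones were the reductases comp12994_c0, HMG2 (comp13449_c0) and HMG1 (comp7117_c0), named after their values were seen. HMGR1 (comp24342_c0, 3.15 ± 0.60), a reductase at the committed step of that pathway, reached 39.6 ± 26.9 CPM in root and 4.45 ± 1.77 in leaf. Mvd (comp22355_c0, 2.63 ± 0.46), the decarboxylase that ends the pathway, reached 164 ± 53.5 and 26.5 ± 6.41.

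Cytochrome P450 enzymes, which oxidise terpenoids and other metabolites, went both ways, as 28 of 149 genes tested were higher in root, 20 were lower and 101 did not pass (48 higher and 35 lower adjusted over the list alone). CYP716B2 (comp23094_c0, 3.55 ± 0.72), of a family known from triterpene oxidation, and comp23146_c0 (4.20 ± 0.82) were higher in root. CYP716B2 (comp22273_c0, -3.72 ± 0.74), of the same symbol as the first, and CYP86A2 (comp22420_c0, -8.54 ± 0.69), a fatty acid hydroxylase of cutin formation, were lower. Among UDP-glycosyltransferases, which attach sugars to small molecules such as monoterpenols, 8 of 76 genes tested were higher in root, 8 were lower and 60 did not pass (9 higher and 8 lower adjusted over the list alone). UGT85A3 (comp19699_c0, 7.96 ± 1.63) and UGT88A1 (comp21364_c0, 10.33 ± 2.39) were higher in root. UGT85A1 (comp21401_c0, -4.22 ± 0.68) and UGT82A1 (comp22040_c0, -4.23 ± 0.39) were lower. Terpene synthases listed by gene product split as well, as 2 of 23 genes tested were higher in root, 6 were lower and 15 did not pass (6 higher and 9 lower adjusted over the list alone). Of the IDs described as 1,8-cineole synthase, a monoterpene-forming enzyme, VIT_19s0014g04930 (comp23266_c0, 2.64 ± 0.52) and VIT_19s0014g04930 (comp23214_c0, 6.05 ± 0.75) were higher in root. comp19097_c0 (-7.12 ± 1.69) and VIT_19s0014g04930 (comp21880_c0, -3.87 ± 0.97) were lower. In the fixed list of conserved microRNA targets, whose 16 members were all TCP genes, regulators of leaf growth, 5 of 16 genes tested were lower in root and 11 did not pass (5 lower adjusted over the list alone). TCP3 (comp15661_c0, -5.25 ± 0.32) and TCP2 (comp22272_c0, -4.13 ± 0.80) were lower, with another TCP3 (comp11574_c0), TCP9 (comp18885_c0) and TCP5 (comp21685_c0), named after their values were seen. A wider list of microRNA target factors by symbol went the other way, as 12 of 60 genes tested were higher in root, 4 were lower, all of them TCP genes above, and 44 did not pass (17 higher and 4 lower adjusted over the list alone). In the heat shock list, 17 of 83 genes tested were higher in root, 2 were lower and 64 did not pass (26 higher and 4 lower adjusted over the list alone). The small heat shock protein HSP18.1 (comp23098_c0, 11.31 ± 2.34) reached 5241 CPM in root replicate 1 and 374 in root replicate 2. HSP26-A (comp11478_c0, 7.71 ± 1.54), named as a heat shock protein and described as a glutathione S-transferase, was higher too. The chaperone HSP90-1 (comp22946_c0, -2.23 ± 0.46) and comp26087_c0 (-3.23 ± 0.39), described as HspQ, were lower. Among fermentation genes, which serve energy metabolism without oxygen, 5 of 12 genes tested were higher in root and 7 did not pass (8 higher adjusted over the list alone). The alcohol dehydrogenase ADH2 (comp18825_c1, 6.82 ± 1.19) and PDC1 (comp21661_c0, 1.90 ± 0.47), a pyruvate decarboxylase by symbol, were higher, with the dehydrogenases ADH (comp19274_c0) and ADH1 (comp20134_c0 and comp21492_c0), named after their values were seen.

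Without counts in leaf and higher in root were the endoglucanase CEL1 (comp18690_c0, at least 7064-fold), the laccases LAC14 (comp17050_c0, at least 3522-fold) and LAC9 (comp20470_c0, at least 1682-fold), enzymes of lignin polymerisation, and the DNA-binding genes ESC (comp8064_c0, at least 2128-fold) and ESC (comp4801_c0, at least 1726-fold). Without counts in root and lower there were PGR5 (comp14089_c0, at least 4418-fold) and ndhN (comp19318_c0, at least 3792-fold) of cyclic electron flow, the ferredoxin reductase PETH (comp16101_c2, at least 3458-fold) and the phosphomannomutase comp13582_c0 (at least 3805-fold). Set tests passed for photosynthesis (median -9.59, camera adjusted p = 6.66e-36), MVA (median 1.07, camera adjusted p = 6.77e-04), heat shock (median 1.42, at bound 1.37, camera adjusted p = 0.0016), fermentation (median 2.56, camera adjusted p = 0.00102) and TCP genes (median -0.52, camera adjusted p = 0.0189). These were lost at adjusted p = 0.126, 0.58, 0.58, 0.34 and 0.58 with an estimated correlation, in the same order. With camera they did not pass for P450s, UDP-glycosyltransferases or terpene synthases by product (camera adjusted p = 0.476, 0.607 and 0.174). Fry passed terpene synthases by product as lower (fry adjusted p = 0.00572), and camera with an estimated correlation did not (adjusted p = 0.427). Among transcription factors, 30 of 259 genes tested were higher in root, 12 were lower and 217 did not pass (42 higher and 16 lower adjusted over the list alone). Among cell cycle genes, 11 of 187 genes tested were higher in root, 10 were lower and 166 did not pass (11 higher and 10 lower adjusted over the list alone). Both lists passed the set test: transcription factors (median 0.84, at bound 0.74, camera adjusted p = 0.0016) and the cell cycle (median 0.71, camera adjusted p = 0.00242). Both were lost at adjusted p = 0.58 and 0.58 with an estimated correlation. Set tests also passed as higher for lists by symbol of microRNA target factors (median 1.24, camera adjusted p = 0.00102) and auxin response (median 1.27, at bound 1.23, camera adjusted p = 0.00219), and for root transport (median 1.20, camera adjusted p = 0.0221). These were lost at adjusted p = 0.111, 0.276 and 0.348 with an estimated correlation. In the auxin list by symbol, 13 of 65 genes tested were higher in root, 7 were lower and 45 did not pass. The fixed auxin list pointed the other way, as 3 of 13 genes tested were higher in root, 5 were lower and 5 did not pass. Its set test did not pass with camera (median -0.40, camera adjusted p = 0.245), whereas fry passed it as lower (fry adjusted p = 0.0268). In the root transport list, 10 of 64 were higher and 50 did not pass, and 4 were lower, namely TIP3-1 (comp15140_c0), NRT1.7 (comp17806_c0), NRT1.2 (comp3767_c0) and NRT1.4 (comp9949_c0), named after their values were seen. The housekeeping controls passed as higher too, with a median near that of the cell cycle (0.72, camera adjusted p = 0.0189; adjusted p = 0.589 with an estimated correlation). Of 93 controls tested, ACT1 (comp16535_c0), TUBA (comp18855_c0) and TUBA2 (comp18855_c1) were higher in root, GAPA (comp14930_c0), GAPB (comp11576_c0 and comp11576_c1) and GAPN (comp8084_c0) were lower, all named after their values were seen, and 86 did not pass. Organelle-encoded transcripts passed as lower (7 of 21 genes tested lower in root, camera adjusted p = 0.0017; adjusted p = 0.58 with an estimated correlation), with a median of -0.29 that was 0.016 under total scaling, or -0.38 and -0.53 relative to the median of all genes. Among ribosomal protein genes, 1 of 331 genes tested was higher in root, 29 were lower and 301 did not pass (27 lower adjusted over the list alone). Their set test passed as lower (median -0.17, at bound -0.16, camera adjusted p = 0.0223; adjusted p = 0.785 with an estimated correlation), but their median was 0.15 under total scaling and 0.06 on TPM, or -0.40 and -0.28 relative to the median of all genes. Of the lists that passed with camera, fry did not pass the cell cycle, housekeeping controls or ribosomal proteins (fry adjusted p = 0.0678, 0.306 and 0.212). In all, 1242 genes were higher and 2213 lower in root (35.9% higher), and 7553 of 27939 had an unadjusted p under 0.05. No counts in the other tissue were found for 179 of the higher and 243 of the lower genes. The share higher was 53.2% under total scaling without the 20 highest genes and 50.3% on log2(TPM + 1), which moved the median of all genes from 0.09 to 0.55 and 0.34. Without root replicate 1, leaf replicate 1 and leaf replicate 2 in turn, 2285, 1524 and 1412 genes passed for root against leaf.

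Root against flower addressed genes that separate the root from reproductive organs. Many floral MADS regulators and some phenylpropanoid, flavonoid and cell wall genes were lower in root, whereas many P450s were higher. In the floral MADS list, 5 of 21 genes tested were higher in root, 10 were lower and 6 did not pass (6 higher and 11 lower adjusted over the list alone), with a median log2 fold change of -3.85. GLO (comp18082_c0, -14.45 ± 1.16), a petal and stamen identity gene, reached 887 ± 172 CPM in flower and 0.0358 ± 0.022 in root, and FBP2 (comp5191_c0, -9.88 ± 1.30), a SEPALLATA-type partner, was lower as well. The list also matched MADS genes with other roles, and SOC1 (comp25395_c0, 3.40 ± 0.40), a flowering-time integrator, and AG1 (comp18001_c0, at least 3.86-fold), a carpel identity gene, were higher in root, the latter at 0.241 ± 0.0026 CPM, as were SVP (comp10418_c0), MADS27 (comp19764_c0) and AGL12 (comp3886_c0), named after their values were seen. Among phenylpropanoid genes, 1 of 35 genes tested was higher in root, 8 were lower and 26 did not pass (2 higher and 8 lower adjusted over the list alone). PAL (comp23045_c0, -2.29 ± 0.52), the entry enzyme, and 4CLL10 (comp22918_c0, -5.08 ± 0.71), a ligase-like gene, were lower. The reductase CCR2 (comp17051_c0, 77.0-fold, counting interval 26.2 to 375) was higher. On log2(TPM + 1) the log2 fold change of PAL was 0.21, and it was -0.48 (not passing) with median-ratio scaling of the TPM. The effective length implied by its counts and TPM was 2834 and 2758 bases in flower and 781 to 1051 elsewhere. Among flavonoid genes, 4 of 31 genes tested were higher in root, 6 were lower and 21 did not pass (7 higher and 9 lower adjusted over the list alone). FLS (comp15278_c0, -13.12 ± 1.05), which forms flavonols, reached 1199 ± 298 CPM in flower and 0.132 ± 0.0421 in root, and the hydroxylase FHT (comp20658_c0, -4.35 ± 0.83) was lower too. A chalcone synthase, comp16436_c0 (10.43 ± 2.08), and the flavonoid hydroxylase CYP75B2 (comp21230_c0, 6.28 ± 0.93) were higher, the former at 2532 CPM in root replicate 1 and 84.7 in replicate 2.

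Among P450 genes, 42 of 149 genes tested were higher in root, 11 were lower and 96 did not pass (55 higher and 18 lower adjusted over the list alone). CYP716B2 (comp23094_c0, 7.45 ± 0.87) and CYP72A1 (comp22391_c0, 4.22 ± 0.96), described as ent-kaurene oxidase, were higher in root. CYP86A2 (comp22420_c0, -11.97 ± 0.78) and CYP77A3 (comp22341_c0, -1.89 ± 0.43), both of families known from cutin formation, were lower. Among UDP-glycosyltransferases, 11 of 76 genes tested were higher in root, 14 were lower and 51 did not pass (19 higher and 17 lower adjusted over the list alone). UGT85A3 (comp19699_c0, 9.92 ± 1.78) and UGT85A2 (comp22118_c0, 8.63 ± 2.16) were higher. UGT73C3 (comp11497_c0, -6.21 ± 0.76) and UGT74F2 (comp22897_c0, -6.28 ± 1.02) were lower. Among cell wall remodelling genes, 13 of 126 genes tested were higher in root, 33 were lower and 80 did not pass (18 higher and 35 lower adjusted over the list alone). The xyloglucan enzymes XTH6 (comp22888_c1, -8.52 ± 1.27) and XTHB (comp21386_c0, -7.12 ± 0.88) reached 8725 ± 4509 and 4107 ± 1571 CPM in flower, whereas the polygalacturonase At1g48100 (comp5132_c0, 12.10 ± 0.96) and the pectinesterase PME47 (comp21280_c0, 11.23 ± 2.31) were higher in root. In the pollen list, whose 5 members were all SF3 genes for pollen-associated LIM proteins, 2 of 5 genes tested were lower in root and 3 did not pass (4 lower adjusted over the list alone), and the lower ones were SF3 (comp14862_c0, at least 538-fold) and SF3 (comp12409_c0, at least 112-fold). A wider list of pollen growth and maturation by GO term did not pass, as 7 of 75 genes tested were higher in root, 7 were lower and 61 did not pass (median 0.12, camera adjusted p = 0.927). Among MVA genes, 5 of 16 genes tested were higher in root, 1 was lower and 10 did not pass (6 higher and 2 lower adjusted over the list alone). Mvd (comp22355_c0, 1.84 ± 0.45) and the reductase HMG2 (comp7930_c0, 5.09 ± 1.10) were higher, with the reductases comp12994_c0 and HMGR (comp7583_c0) among the others, named after their values were seen, and HMGR1 (comp24342_c0, -3.65 ± 0.61), another reductase, was lower. Among terpene synthases by product, 4 of 23 genes tested were higher in root, 3 were lower and 16 did not pass (4 higher and 3 lower adjusted over the list alone). comp15294_c0 (9.71 ± 1.40) and VIT_19s0014g04930 (comp21880_c0, 6.24 ± 1.15) were higher in root. comp19097_c0 (-13.53 ± 2.02) and VIT_19s0014g04930 (comp28580_c0, -7.75 ± 1.61) were lower.

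Without counts in flower and higher in root were the germin-like GLP6 (comp16258_c0, at least 2056-fold), the P450 CYP87A3 (comp6109_c0, at least 1717-fold), the small heat shock gene HSP26.5 (comp18977_c0, at least 1371-fold), the proanthocyanidin enzyme LAR (comp6581_c0, at least 1327-fold) and ESC (comp8064_c0, at least 1119-fold). With at most 3 counts in root and lower there were the floral regulator MYB305 (comp14131_c0, 133999-fold, counting interval 24049 to 5292780.0), MLP423 (comp18807_c0, 97690.2-fold, counting interval 33427 to 473715) of the major latex proteins, the MADS gene FBP1 (comp12071_c0, at least 6784-fold), the kinase PERK10 (comp14135_c0, at least 4834-fold) and the spermidine acyltransferase SHT (comp20955_c0, at least 4727-fold). Among photosynthesis genes, 1 of 69 genes tested was higher in root, 21 were lower and 47 did not pass (2 higher and 28 lower adjusted over the list alone), the higher one being the Rubisco methyltransferase RBCMT (comp17332_c0), named after its value was seen. Among TCP genes, 7 of 16 genes tested were lower in root and 9 did not pass (9 lower adjusted over the list alone). Among heat shock genes, 22 of 83 genes tested were higher in root, 2 were lower and 59 did not pass (31 higher and 3 lower adjusted over the list alone). In the fixed auxin response list, 7 of 13 genes tested were lower in root and 6 did not pass (7 lower adjusted over the list alone). The wider auxin list by symbol went both ways, as 10 of 65 genes tested were higher in root, 16 were lower and 39 did not pass (median 0.24, camera adjusted p = 0.752). In the microRNA target list by symbol, 15 of 60 genes tested were higher in root, 6 were lower and 39 did not pass (camera adjusted p = 0.11). Among cell cycle genes, 29 of 187 genes tested were higher in root, 12 were lower and 146 did not pass (35 higher and 14 lower adjusted over the list alone). Set tests passed for MADS genes (median -3.85, camera adjusted p = 0.00834), phenylpropanoid genes (median -1.10, camera adjusted p = 0.0142), P450s (median 1.85, at bound 1.75, camera adjusted p = 0.00222), cell wall genes (median -0.78, camera adjusted p = 0.0116) and SF3 genes (median -1.76, camera adjusted p = 0.00997), and the cell wall median was 0.00 on TPM, or -0.77 relative to the median of all genes. They were lost at adjusted p = 0.368, 0.257, 0.257, 0.435 and 0.257 with an estimated correlation, in the same order. They also passed for photosynthesis (median -2.69, camera adjusted p = 1.42e-06), TCP genes (median -2.61, camera adjusted p = 7.80e-05), heat shock (median 1.85, at bound 1.75, camera adjusted p = 0.00165), auxin response (median -1.16, camera adjusted p = 0.00834) and the cell cycle (median 0.86, at bound 0.80, camera adjusted p = 0.0255). These were lost at adjusted p = 0.368, 0.257, 0.435, 0.475 and 0.603 with an estimated correlation. With camera they did not pass for flavonoid, MVA and UDP-glycosyltransferase genes or terpene synthases by product (camera adjusted p = 0.0839, 0.182, 0.982 and 0.777). Fry passed flavonoid genes as lower (fry adjusted p = 0.0066), and camera with an estimated correlation did not (adjusted p = 0.368). In all, 2624 genes were higher and 3120 lower in root (45.7% higher), and 10305 had an unadjusted p under 0.05. No counts in the other tissue were found for 553 of the higher and 373 of the lower genes. The share higher was 71.7% under total scaling without the 20 highest genes and 76.2% on log2(TPM + 1), which moved the median of all genes from 0.17 to 0.86 and 0.77. Without root replicate 1, root replicate 2, leaf replicate 2, flower replicate 1 and flower replicate 2 in turn, 2854, 3411, 3804, 1.8e+03 and 2841 genes passed for root against flower.

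Root against fruit addressed genes that separate these tissues at their different periods. Some photosynthesis and floral MADS genes were lower in root, and 3 aquaporins, some P450s and a plastid isoprenoid enzyme were higher. In the photosynthesis list, 16 of 69 genes tested were lower in root and 53 did not pass (2 higher and 47 lower adjusted over the list alone), with a median log2 fold change of -4.79. RBCS (comp23363_c0, -9.41 ± 1.21) reached 1689 ± 1183 CPM in fruit and 2.47 ± 1.37 in root, and PSAL (comp15807_c0, -9.04 ± 0.98), a photosystem I subunit, was lower too. Among MADS genes, 3 of 21 genes tested were higher in root, 6 were lower and 12 did not pass (5 higher and 10 lower adjusted over the list alone), with a median log2 fold change of -4.46, or -3.15 with genes at 0 at their bound. FBP2 (comp5191_c0, -7.40 ± 1.19) and DEFA (comp20901_c0, -6.54 ± 1.08), the latter of petal and stamen identity, were lower. SOC1 (comp25395_c0, 4.73 ± 0.43) and AGL12 (comp3886_c0, 3.81 ± 0.60), a root MADS gene in other plants, were higher, as was MADS27 (comp19764_c0), named after its value was seen. In the fixed auxin list, 2 of 13 genes tested were lower in root and 11 did not pass (5 lower adjusted over the list alone), and the lower ones were the conjugating enzyme GH3.5 (comp7449_c0, -2.27 ± 0.39) and the transporter PIN8 (comp5602_c0, -6.02 ± 0.63). In the wider auxin list by symbol, 4 of 65 genes tested were higher in root, 1 was lower, again GH3.5, and 60 did not pass (median 0.44, camera adjusted p = 0.111). The higher ones were the response factors ARF4 (comp16192_c0 and comp21084_c0), ARF15 (comp19854_c0) and ARF5 (comp47611_c0), named after their values were seen. Among P450 genes, 10 of 149 genes tested were higher in root, 2 were lower and 137 did not pass (23 higher and 13 lower adjusted over the list alone). CYP71A1 (comp6371_c0, 8.16 ± 1.27) and CYP71A1 (comp16766_c0, 8.70 ± 1.42), of a family with roles in terpenoid oxidation, were higher, and the fatty acid hydroxylase CYP94A1 (comp21882_c0, -3.52 ± 0.47) and CYP87A3 (comp19106_c0, -7.98 ± 1.20) were lower. Among UDP-glycosyltransferases, 2 of 76 genes tested were higher in root, 3 were lower and 71 did not pass (6 higher and 11 lower adjusted over the list alone). UGT85A3 (comp19699_c0, 10.57 ± 1.82) and UGT74E2 (comp21126_c0, 3.02 ± 0.35) were higher. UGT74F1 (comp6591_c0, -3.62 ± 0.66) and UGT92A1 (comp18959_c0, at least 11.8-fold) were lower, as was UGT72E3 (comp12195_c1), named after its value was seen.

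In the methylerythritol phosphate (MEP) list, which supplies plastid isoprenoids and so most monoterpenes, 1 of 10 genes tested was higher in root and 9 did not pass (5 higher adjusted over the list alone), with a median log2 fold change of 2.15. The member that passed was Os07g0190000 (comp20919_c0, 8.34 ± 1.41), a deoxyxylulose phosphate synthase at the entry of the pathway, at 289 CPM in root replicate 1, 28.5 in root replicate 2 and 0.488 ± 0.0693 in fruit. In the MVA list, 1 of 16 genes tested was lower in root and 15 did not pass (2 lower adjusted over the list alone), with a median log2 fold change of -0.85, and HMGS (comp8081_c0, -2.71 ± 0.41), an HMG-CoA synthase, was the lower one. Among terpene synthases by product, 1 of 23 genes tested was higher in root, 1 was lower and 21 did not pass (2 higher and 1 lower adjusted over the list alone), namely comp15294_c0 (7.13 ± 1.25) and VIT_19s0014g04930 (comp16860_c0, at least 54.2-fold) in that order. Among root transport and peroxidase genes, 4 of 64 genes tested were higher in root and 60 did not pass (13 higher and 4 lower adjusted over the list alone). The aquaporins PIP2-2 (comp23455_c0, 5.99 ± 0.67) and TIP1-3 (comp20608_c0, 6.43 ± 0.82) were higher, with the aquaporin TIP1-1 (comp12099_c0) and the nitrate transporter NRT2.4 (comp22908_c0), named after their values were seen. With at most 3 counts in fruit and higher in root were the P450 CYP82A3 (comp7605_c1, 23493-fold, counting interval 4216 to 927967), the laccase LAC3 (comp22094_c0, at least 1222-fold), the boundary regulator LBD4 (comp13389_c0, at least 484-fold), the gibberellin-responsive GAST1 (comp15214_c0, at least 369.9-fold) and ESC (comp4801_c0, 3103-fold, counting interval 859 to 25625). With at most 3 counts in root and lower there were the MADS genes AGL1 (comp12596_c0, at least 1275-fold) and SEP1 (comp21161_c0, at least 388-fold), the zinc finger gene ZFP2 (comp10598_c0, at least 1314-fold), the glutamate dehydrogenase GDH2 (comp12984_c0, at least 1290.3-fold) and the nudix hydrolase NUDT8 (comp19485_c0, 1702-fold, counting interval 305 to 67254). Among seed storage genes, 0 of 9 genes tested passed by edgeR, with 0 higher and 9 lower at an unadjusted p under 0.05 (8 lower adjusted over the list alone, 0 higher and 8 lower by DESeq2, 0 and 0 by limma), with a median log2 fold change of -14.09, or -13.98 with genes at 0 at their bound, and their level in fruit rested on fruit replicate 2, where the globulin GY3 (comp17721_c0) had 25609.5 CPM against 14.3 in replicate 1.

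Set tests passed for photosynthesis (median -4.79, camera adjusted p = 2.59e-22), auxin response (median -2.27, at bound -1.27, camera adjusted p = 5.83e-05), MEP (median 2.15, camera adjusted p = 2.38e-04), MVA (median -0.85, camera adjusted p = 0.00742), MADS (median -4.46, at bound -3.15, camera adjusted p = 0.0357), seed storage (median -14.09, at bound -13.98, camera adjusted p = 1.11e-04) and root transport (median 0.91, at bound 0.82, camera adjusted p = 0.0012). These were lost at adjusted p = 0.293, 0.57, 0.57, 0.57, 0.57, 0.378 and 0.378 with an estimated correlation, in the same order. Set tests also passed as higher for the cell cycle (median 0.54, camera adjusted p = 4.27e-04) and housekeeping (median 0.40, camera adjusted p = 0.0108). These were lost at adjusted p = 0.57 and 0.57 with an estimated correlation. Of the 7 fixed lists that passed with camera for root against fruit, fry kept 3. Among cell cycle genes, 0 of 187 genes tested passed by edgeR, with 37 higher and 7 lower at an unadjusted p under 0.05 (0 adjusted over the list alone, 17 higher and 6 lower by DESeq2, 11 and 3 by limma). Among housekeeping genes, 4 of 93 genes tested were lower in root and 89 did not pass (4 lower adjusted over the list alone), and the lower ones were GAPA (comp14930_c0), GAPB (comp11576_c0 and comp11576_c1), plastid dehydrogenases of carbon fixation, and kinX (comp15610_c0), described as a chromatin regulator, all named after their values were seen. The test did not pass for P450s, UDP-glycosyltransferases or terpene synthases by product (camera adjusted p = 0.44, 0.123 and 0.838). For terpene synthases by product the median was -0.31 and the mean -0.55, while the set test pointed up. With genes at 0 at their bound, and those with at most 3 counts in both tissues set to 0, the median was 0 and the mean 0.11. The negative values thus rested on fitted folds of IDs with few or no counts. In all, 228 genes were higher and 347 lower in root (39.7% higher), and 5073 had an unadjusted p under 0.05. No counts in the other tissue were found for 15 of the higher and 53 of the lower genes. The share higher was 55.2% on log2(TPM + 1), where the median of all genes was 0.16. With only the root and fruit libraries in the fit, 0 genes passed by edgeR, against 4410 at an unadjusted p under 0.05, and 3281 passed by DESeq2 in all 8 libraries. Without root replicate 1, leaf replicate 1, leaf replicate 2, flower replicate 1, flower replicate 2, fruit replicate 1 and fruit replicate 2 in turn, 151, 199, 165, 258, 255, 138 and 103 genes passed for root against fruit.

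**Figure D3:**
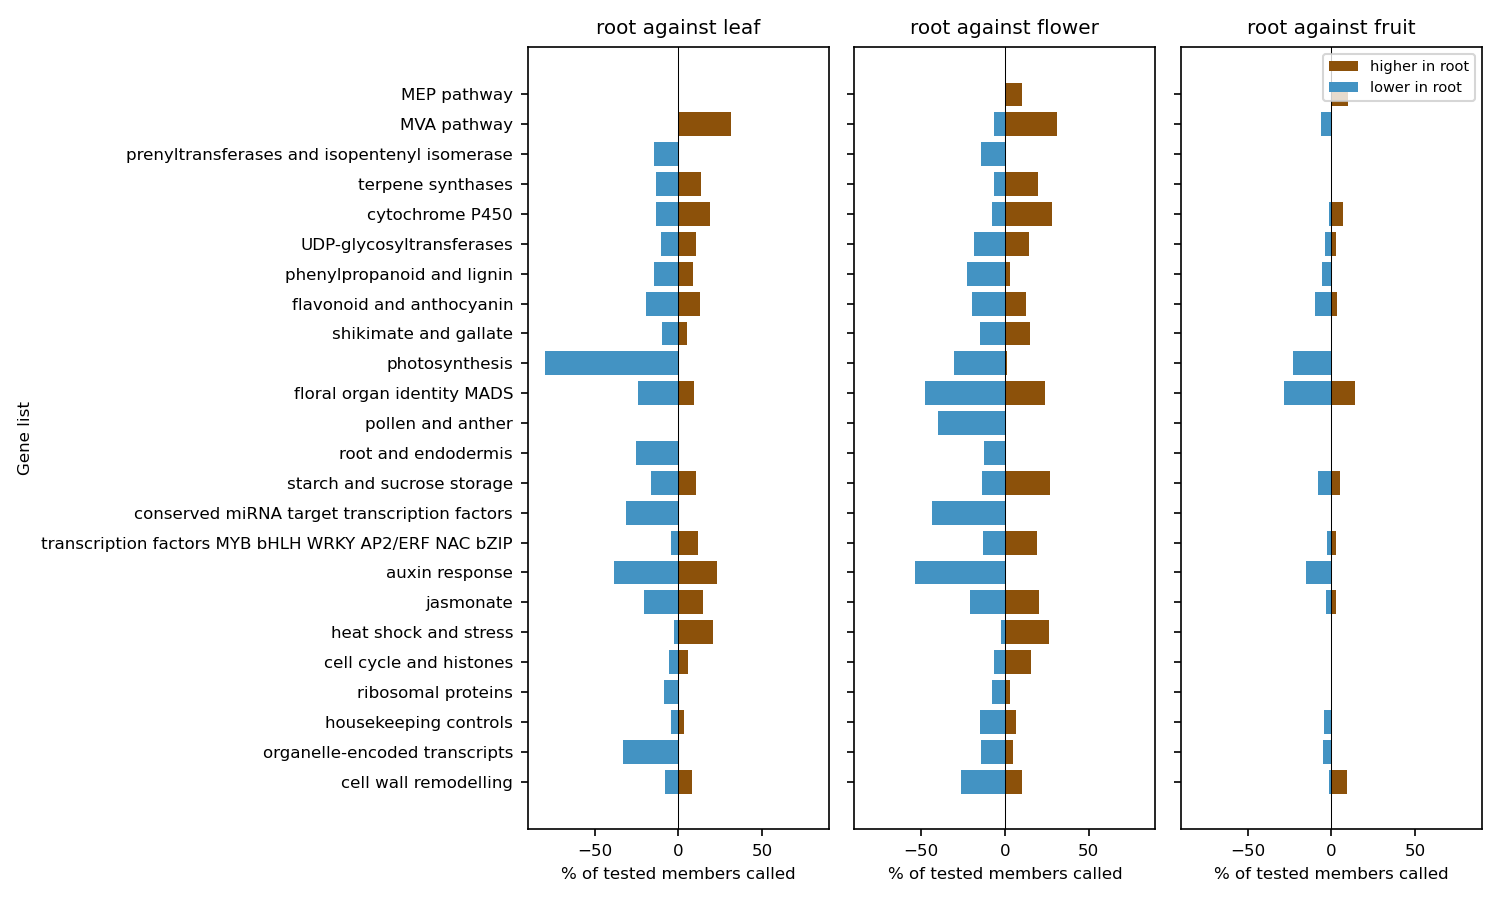
Bars give the percentage of tested members of each fixed list that passed as higher (right) or lower (left, negative values) in root, for root against leaf, flower and fruit. Photosynthesis had 55, 21 and 16 members lower in root.

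The precursor pathways were followed enzyme by enzyme, as the ID with the highest mean, with log2 fold changes of root against leaf, flower and fruit in that order. In the MEP list, 0 of 10 genes tested passed by edgeR, with 0 higher and 3 lower at an unadjusted p under 0.05 (0 adjusted over the list alone, 0 higher and 2 lower by DESeq2, 0 and 1 by limma) for root against leaf. The median log2 fold change was 0.11, the mean was -0.27 and the set test pointed down without passing (camera adjusted p = 0.316). Against flower the set test did not pass either (camera adjusted p = 0.227), and 1 of 10 genes tested was higher in root and 9 did not pass (0 adjusted over the list alone), namely ISPF (comp15871_c0), the cyclodiphosphate synthase, with 0.50 ± 0.69, 2.99 ± 0.74 and 1.44 ± 0.70. The entry enzyme Os07g0190000 (comp22577_c0) gave 0.77 ± 1.0, -0.93 ± 1.0 and 4.39 ± 1.14, and the reductoisomerase DXR (comp22957_c0) gave -3.20 ± 0.94, 1.07 ± 0.88 and 2.34 ± 0.91. Of the other later steps, ISPD, ISPE, ISPG and ISPH did not pass in any of these comparisons. ISPD (comp15693_c0) gave -1.49 ± 0.51, 0.00 ± 0.50 and 0.98 ± 0.50, and ISPE (comp17283_c0) gave -0.21 ± 0.56, 1.71 ± 0.57 and 2.08 ± 0.58. ISPG (comp16115_c0) gave 0.23 ± 0.73, 2.09 ± 0.76 and 2.21 ± 0.76, and ISPH (comp18951_c0) gave -0.00 ± 0.68, 1.54 ± 0.70 and 1.77 ± 0.70. Root replicate 1 stood above root replicate 2 for these enzymes, with 1067 and 85.6 CPM for the entry enzyme, 569 and 89.1 for DXR and 1063 and 197 for ISPG. The differences of ISPE, ISPG, ISPH and comp22577_c0 against leaf and of ISPD against flower changed sign under some other processing. Without root replicate 1, the differences against leaf were -1.98 for comp22577_c0, -1.07 for ISPF and -1.45 for ISPG, those against flower -0.44 for ISPD and -0.81 for DXR, and that of ISPF against fruit -0.13. Against leaf, ISPE was at 0.37 and ISPH at 0.61 without root replicate 2, and ISPH at 0.34 without leaf replicate 2, and against flower ISPD was at -0.12 without flower replicate 2.

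In the MVA list, the thiolase At5g47720 (comp19528_c0) gave 1.12 ± 0.47, 0.30 ± 0.47 and -2.59 ± 0.49. Its difference from fruit missed the test (adjusted p = 0.0542). The synthase HMGS (comp17997_c0) gave 1.01 ± 0.66, 0.45 ± 0.65 and -2.35 ± 0.68, and the reductase comp23063_c0 gave 0.24 ± 0.76, -0.38 ± 0.76 and -2.05 ± 0.79. The kinase At5g27450 (comp22839_c0) gave 0.49 ± 0.44, -1.30 ± 0.45 and 0.07 ± 0.44, and the second kinase erg8 (comp22716_c0) gave 0.77 ± 0.35, 0.58 ± 0.35 and -0.61 ± 0.35. These 5 enzymes did not pass in any of these comparisons. The signs of comp23063_c0 against flower and At5g27450 against fruit changed under some other processing. Without root replicate 2, comp23063_c0 was at -0.054 and HMGS at -0.039 against leaf, and HMGS at -0.51 and At5g47720 at -0.087 against flower. Without leaf replicate 2, comp23063_c0 was at -0.50 against leaf. Against fruit, At5g27450 was at -0.16, -0.0088 and -0.54 without root replicate 1, leaf replicate 2 and fruit replicate 2. Mvd (comp22355_c0) passed against leaf and flower, and gave 2.63 ± 0.46, 1.84 ± 0.45 and -0.91 ± 0.44. Of the prenyltransferases and isomerases, 1 of 7 members was lower in root against leaf and 1 against flower, in both GGR (comp20102_c0), named after its values were seen (camera adjusted p = 0.955 and 0.404). Against fruit, 0 of 7 genes tested passed by edgeR, with 1 higher and 2 lower at an unadjusted p under 0.05 (1 higher and 2 lower adjusted over the list alone, 1 higher and 2 lower by DESeq2, 1 and 2 by limma). The set test against fruit did not pass (camera adjusted p = 0.44). The isomerase IPI2 (comp12361_c0) gave 0.98 ± 0.43, -0.76 ± 0.43 and -0.26 ± 0.43. At3g14510 (comp17723_c0), described as farnesyl diphosphate synthase, gave 1.64 ± 0.88, -1.45 ± 0.87 and 5.30 ± 1.03, the last with an adjusted p = 0.0565. The fixed terpene synthase list held mostly trehalose genes matched by the symbol TPS. Against leaf, 2 of 15 genes tested were higher in root, 2 were lower and 11 did not pass (4 higher and 2 lower adjusted over the list alone). Against flower, 3 of 15 genes tested were higher in root, 1 was lower and 11 did not pass (3 higher and 2 lower adjusted over the list alone). Against fruit, 0 of 15 genes tested passed by edgeR, with 2 higher and 2 lower at an unadjusted p under 0.05 (0 adjusted over the list alone, 2 higher and 2 lower by DESeq2, 0 and 1 by limma). The set tests did not pass (camera adjusted p = 0.495, 0.869 and 0.404). Of its IDs with the highest means, TPS11 (comp21713_c1), a 1,8-cineole synthase, gave -0.84 ± 1.51, -5.41 ± 1.81 and -1.73 ± 1.54. The trehalose genes TPS6 (comp21039_c0) and TPS5 (comp22816_c0) gave 2.01 ± 0.37, 2.05 ± 0.37 and 0.14 ± 0.35, and 0.86 ± 0.57, 4.34 ± 0.65 and 1.85 ± 0.58. The signs of IPI2 against flower, TPS11 against leaf and TPS6 against fruit changed under some other processing. Against leaf, At3g14510 was at -0.10 and TPS5 at -0.031 without root replicate 1, and TPS11 at 2.30 without leaf replicate 1. Against fruit, IPI2 was at 0.016 and TPS6 at -0.075 without root replicate 2, and TPS6 at -0.19 without fruit replicate 2.

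**Figure D4:**
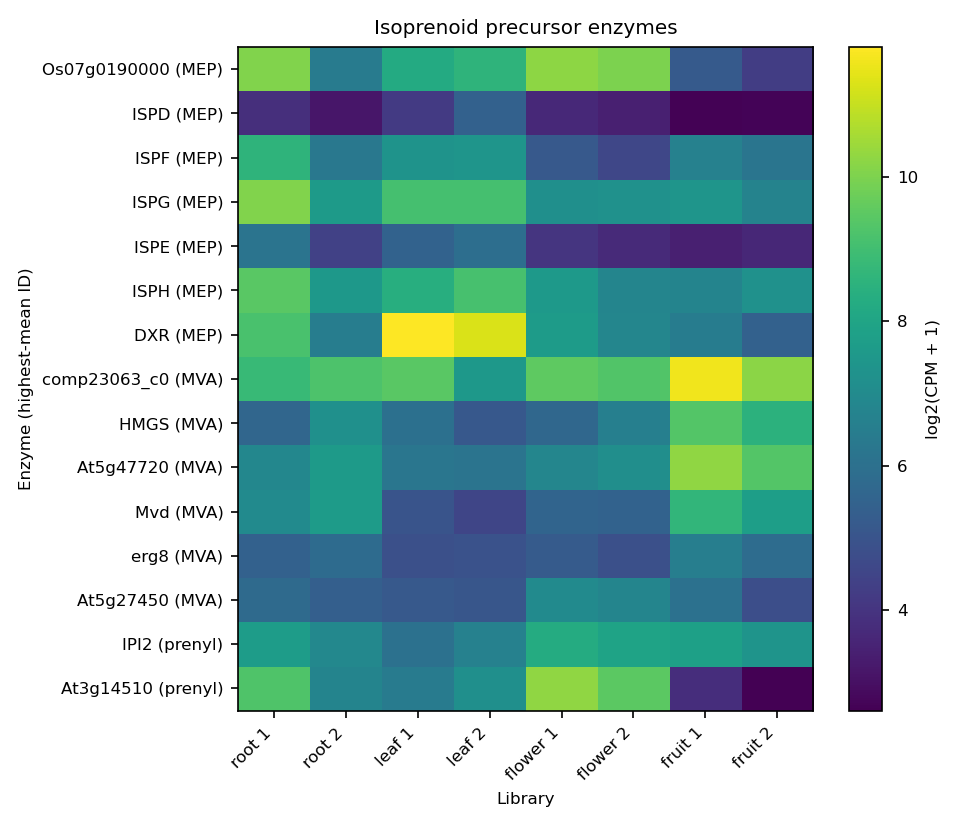
Colour gives log2(CPM + 1) of the highest-mean IDs of enzymes of the MEP, MVA and prenyltransferase lists (y axis) in each of the 8 libraries (x axis). Root replicate 1 had 569 CPM of DXR and root replicate 2 had 89.1 CPM.

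Among the other tissues, leaf against flower gave 2794 genes higher and 2604 lower in leaf (51.8% higher, or 68.3% on log2(TPM + 1)). PETH (comp16101_c1, at least 3129.7-fold), ndhN (comp19318_c0, at least 1688-fold) and comp13582_c0 (at least 1694-fold) were higher in leaf and without counts in flower. The petal genes GLO (comp18082_c0, at least 27939-fold) and FBP1 (comp12071_c0, at least 5741-fold) and the arabinogalactan gene FLA14 (comp20178_c0, at least 4382-fold) were lower and without counts in leaf. Leaf against fruit gave 1691 genes higher and 1003 lower in leaf (62.8% higher, or 46.6% under total scaling without the 20 highest). The Rubisco small subunit RBCS (comp14908_c0, at least 12154-fold), GAST1 (comp15214_c0, at least 9060.2-fold) and the hydroxypyruvate reductase HPR3 (comp5229_c0, at least 8059-fold) were higher in leaf. The oleosin OLE1 (comp23438_c0, 54245-fold, counting interval 18561 to 263042), MATP6-A (comp6808_c0, 28537-fold, counting interval 9764 to 138379) and HSD1 (comp7508_c0, 28639-fold, counting interval 7928 to 236486) were lower. These last genes rested on fruit replicate 2, where OLE1 had 4752 CPM against 5.08 in fruit replicate 1. Flower against fruit gave 4111 genes that passed, 2252 of them higher in flower (54.8%, or 28.3% under total scaling without the 20 highest and 32.8% on log2(TPM + 1)). BHLH135 (comp8132_c0, at least 15679.8-fold), FBP1 (comp12071_c0, at least 6881-fold) and the transporter ABCG12 (comp22608_c0, 88193-fold, counting interval 15828 to 3483510.0) were higher in flower. WRKY27 (comp18956_c0, at least 1230.5-fold), UGT90A1 (comp15558_c0, at least 1082-fold) and WNK5 (comp16945_c0, 22930.3-fold, counting interval 4115 to 905716) were lower. In the MVA list, 9 of 16 genes tested were lower in leaf and 7 did not pass (12 lower adjusted over the list alone) for leaf against fruit. For flower against fruit, 1 of 16 genes tested was higher in flower, 8 were lower and 7 did not pass (2 higher and 11 lower adjusted over the list alone), and the higher one was HMGR1 (comp24342_c0), named after its value was seen. The MVA set tests passed (medians -3.47 and -2.33, camera adjusted p = 1.16e-08 and 0.00123) and were lost at adjusted p = 0.306 and 0.392 with an estimated correlation. In the MEP list for leaf against fruit, 3 of 10 genes tested were higher in leaf and 7 did not pass (9 higher adjusted over the list alone), and the higher ones were ISPD (comp15693_c0), Os07g0190000 (comp20919_c0) and DXR (comp22957_c0), named after their values were seen. The MEP set test passed (median 2.38, camera adjusted p = 5.30e-05, adjusted p = 0.475 with an estimated correlation). Without leaf replicate 1, leaf replicate 2, flower replicate 1 and flower replicate 2 in turn, 1889, 1328, 2073 and 2793 genes passed for leaf against flower. Without leaf replicate 1, leaf replicate 2, fruit replicate 1 and fruit replicate 2 in turn, 489, 261, 835 and 351 genes passed for leaf against fruit. Without leaf replicate 1, leaf replicate 2, flower replicate 1, flower replicate 2, fruit replicate 1 and fruit replicate 2 in turn, 2534, 2414, 936, 1225, 1187 and 1152 genes passed for flower against fruit.

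A contrast of each tissue with the mean of the others, with at least 1 log2 unit above each of them, gave 1308 root-enriched, 2160 leaf-enriched, 2777 flower-enriched and 783 fruit-enriched genes. For each tissue, the annotated genes with the largest contrasts are given with the fold or the levels against the other tissue with the highest mean, or, where all others were at 0, as the lowest of the bounds against them. Root-enriched ones were the P450s CYP82A3 (comp25328_c0, at least 759.6-fold) and CYP82C4 (comp7605_c0, at least 483-fold) and the regulator ESC (comp4801_c0, 3103-fold, counting interval 859 to 25625). Leaf-enriched ones were RBCS (comp14908_c0, 332 ± 262 CPM and 0.136 ± 0.0949 in root), the greening regulator GATA22 (comp20992_c0, at least 600.1-fold) and comp13582_c0 (106 ± 19.4 CPM and 0.668 ± 0.462 in fruit). Flower-enriched ones were FBP1 (comp12071_c0, at least 5741-fold), GLO (comp18082_c0, 887 ± 172 CPM and 0.0358 ± 0.022 in root) and the pectate lyase At2g02720 (comp17679_c0, at least 2789-fold). Fruit-enriched ones were the defence-related STH-21 (comp23908_c0, 20068-fold, counting interval 3601 to 792666), the storage globulin GY3 (comp17721_c0, 12812 ± 18098 CPM and 0.71 ± 0.677 in flower) and the oil body gene HSD1 (comp7508_c0, 837 ± 1183 CPM and 0.0778 ± 0.03 in flower). Fruit replicate 2 held 586 CPM of STH-21 and fruit replicate 1 held 0.732. Without root replicate 1, root replicate 2, leaf replicate 1, leaf replicate 2, flower replicate 1, fruit replicate 1 and fruit replicate 2 in turn, 541, 854, 642, 655, 841, 706 and 807 genes passed as root-enriched. Without leaf replicate 2, 1328 genes passed as leaf-enriched. Without flower replicate 1, 1450 genes passed as flower-enriched. Without root replicate 1, leaf replicate 1, leaf replicate 2, flower replicate 1, flower replicate 2, fruit replicate 1 and fruit replicate 2 in turn, 429, 239, 233, 306, 266, 258 and 187 genes passed as fruit-enriched. Over the 6 pairwise comparisons, camera passed 56 of the tests of 24 fixed lists each, and 0 of these held with an estimated correlation, while fry passed 51. The smallest adjusted p with an estimated correlation was 0.126, for root against leaf.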

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

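The tests of allelic variants and of carry-over were written before their results were seen; the other tests below were chosen after the results they measure were seen. No biological explanation in the labels separates the replicates of a tissue, so that apart from the 2 genotypes below none was tested.

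A set of transcripts followed the replicate number: 137 IDs were present in root, leaf and flower of replicate 1 and at most 2% as high in replicate 2, and 113 the reverse. Random dropout is argued against, since the 6 other assignments of the numbers gave 0 IDs, and so is mixing between same-numbered libraries, since their highest rank correlation over these IDs was 0.577. Allelic variants of one gene held as separate IDs stay open: 0% of the IDs with a symbol in the smaller set shared it with the other, under the bound of 10%, but that bound decides nothing with 7 such IDs and a median of 0 for random sets. RNA of another organism stays open as well, because 6.4% of the IDs had a symbol against 46.7% of all genes tested, which other causes also give. A candidate explanation is plants of 2 genotypes behind the numbers, with fruit from one of them: in fruit replicate 1, 98.8% of the IDs were in the state of number 2, although in fruit replicate 2 it was 78%, with 55 of the 137 IDs of number 1 present at a median ratio of 0.125.

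In fruit replicate 2, 75 IDs that were near absent from root, leaf and flower took 29.6% of the counts, against 0.101% in fruit replicate 1. A mislabelled library of another tissue is argued against, since its correlation with fruit replicate 1 was 0.0985 above the highest with another tissue (0.914 against 0.816). Carry-over of reads as the source of the traces in fruit replicate 1 stays open, because the median trace there was 7.37 times the highest in the other 6 libraries, with a 95% interval of 3.83 to 16.9 that spans the bound of 4. That interval comes from resampling the 75 IDs, so it measures the spread between IDs and neither counting error nor the spread between samples. A later stage of the fruit behind replicate 2 was not tested, as the labels give 1 stage.

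Root replicate 2 lay nearer to fruit than root replicate 1, with correlations with fruit replicate 1 of 0.844 and 0.738. Fruit RNA in the root library is argued against, since over 19 fruit-abundant IDs the 10% quantile of the ratios to fruit was 0.0351 of their median, whereas an admixture sets a common floor. The 250 IDs that follow the replicate number are argued against as the main source of the gap, since without them it was still 0.0884 against 0.105. A wider effect of the replicate number stays open, because only these IDs were removed. Replicate 2 of leaf and of flower also correlated more with fruit replicate 1 than replicate 1 did (0.784 against 0.766 and 0.741 against 0.707).

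IDs outside the tests, removed by the filter, gave a signal far above the 3 counts that a count of 0 allows, at 1000 counts or more in a single library. There was 1 such ID in root replicate 1 (GT5, comp34993_c0), there were 8 in root replicate 2, TIC32 (comp21468_c0) among them, and 3 in flower replicate 1 (comp18012_c0, comp27488_c0 and comp6332_c0). There were 58 in fruit replicate 2, among them CYSEP (comp7746_c0), HSD1 (comp19320_c0) and SUS2 (comp6801_c0), and 0 in the other 4 libraries; these names were chosen after their values were seen.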

How the results depend on the processing

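The tests chosen after the data were seen were limma-trend on log2(TPM + 1), the fit without the TAR1-A IDs, the block with the fruit numbers crossed and the block in camera; the other alternatives were planned. Every comparison rests on 2 libraries per tissue, so that leaving one out leaves a lone library that is assumed to vary like the other groups. Of 142 calls of named genes, 58 passed under every alternative that gave a value, 63 passed with any 1 library left out, and 1 changed direction (PAL, below). The 4 libraries of root and fruit alone gave 0 calls, so that by the construction of that alternative 0 of 32 named calls against fruit passed everywhere, against 15 of 35 against leaf and 22 of 45 against flower. DESeq2's Wald test kept 142 of 142 named calls, DESeq2 size factors 141, no filter on counts 130, limma-trend on log2(CPM + 1) 132, only the 4 libraries compared 73 of 130, glmTreat 102 of 130, total scaling 119 of 125 and the TPM settings 127 to 130 of the 138 to 142 they tested. Of the 51 named results that did not pass, 20 changed direction and 20 passed in at least 1 alternative. Where the cause is not given below, the cause was not tested. The filter removed 2238 IDs, for which no test was made. Their highest count in a library had a median of 36, where depth limits a test, and 70 of them had at least 1000 counts in a single library. Without the filter, and so with more genes to adjust for, the 6 comparisons gave 3075, 5009, 429, 4846, 2313 and 3436 calls.

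The counts of genes past the threshold moved as follows. With the DESeq2 Wald test they were 6006 for root against leaf, 8671 for root against flower, 3281 for root against fruit, 8182 for leaf against flower, 5655 for leaf against fruit and 7282 for flower against fruit. With glmTreat, which tests against the fold threshold itself and is stricter by construction, they were 2266, 3080, 264, 3168, 1544 and 2126 in the same order. Limma-trend on log2(CPM + 1) gave 1590 for root against fruit. With only the 4 libraries compared, edgeR gave 2741 for root against leaf, 5894 for leaf against flower, 3910 for leaf against fruit and 3734 for flower against fruit, some above and some below the counts from all libraries. It gave 2814 for root against flower and 0 for root against fruit, where 4410 genes had an unadjusted p under 0.05; DESeq2 and limma-trend over all libraries gave the 3281 and 1590 above. Limma-trend on log2(TPM + 1) gave 1436 for root against fruit, 2027 root-enriched and 1645 flower-enriched genes. A pseudocount of 0.1 gave 8673 for root against flower, 1211 for root against fruit and 1622 flower-enriched genes. The TPM without a filter gave 1116 for root against fruit and 1600 flower-enriched genes, and the filter of 5 in 2 libraries gave 1439 and 1391. Quantile normalization gave 1602 for root against fruit and 4167 for leaf against fruit, and median-ratio scaling 1416 for root against fruit. Without trend and robust fitting the values were 1661 for root against fruit, 2110 root-enriched and 1660 flower-enriched genes. Of 56 gene set tests that passed with camera at the preset correlation, 0 passed with the estimated correlation and 51 tests passed with fry, 43 of them shared.

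With 1 library left out, the counts ran from 1412 (without leaf replicate 2) to 3094 (flower 1) for root against leaf, from 1.8e+03 (flower 1) to 4804 (fruit 2) for root against flower, and from 103 (fruit 2) to 769 (root 2) for root against fruit. They ran from 1328 (leaf 2) to 5564 (root 1) for leaf against flower, from 261 (leaf 2) to 3183 (root 1) for leaf against fruit, and from 936 (flower 1) to 4277 (root 1) for flower against fruit. Enriched genes numbered 541 (root 1) to 982 (flower 2) for root, 1328 (leaf 2) to 2096 (root 1) for leaf, 1450 (flower 1) to 2670 (root 1) for flower and 187 (fruit 2) to 816 (root 2) for fruit. Without root 1, root 2, leaf 1, leaf 2, flower 1, flower 2, fruit 1 and fruit 2, in this order, 38, 27, 47, 51, 49, 40, 34 and 39 of the 142 named calls no longer passed. The share of genes higher in the first tissue fell to 16.1% for root against leaf without either leaf library, to 34.7% for root against flower without flower 1, and to 7.97% and 7.77% for root against fruit without fruit 1 and fruit 2. It rose to 65.7% and 72.0% for leaf against flower and to 77.9% and 75.9% for leaf against fruit without leaf 1 and leaf 2, and was 45.01% for leaf against fruit without fruit 2. On the TPM it ran, over the settings in which it moved by over 10 points, from 49.3 to 51.1% for root against leaf, 76.1 to 77.0% for root against flower, 49.9 to 57.2% for root against fruit, 68.3 to 70.4% for leaf against flower and 29.0 to 33.7% for flower against fruit, and was 51.6% for leaf against fruit with the pseudocount of 0.1.

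Total scaling without the 20 highest genes moved the median log2 fold change of all genes from 0.13 to 0.36 for leaf against flower, from 0.012 to -0.39 for leaf against fruit and from -0.16 to -0.82 for flower against fruit, and the TPM moved them to 0.45, -0.081 and -0.62. The median of the organelle list for root against leaf, -0.29, became 0.016 with total scaling, and that of the phenylpropanoid list for flower against fruit, 0.53, became -0.16 with total scaling and -0.12 on the TPM; relative to the median of all genes, neither changed sign. With 1 ID per description, which left few IDs in several lists, 30 of 72 percentages of list genes that passed moved by over 1.5 times. For root against leaf, MVA went from 31.3 to 14.3% (7 IDs), UDP-glycosyltransferases from 21.1 to 4.76% (21), prenyltransferases from 14.3 to 0% (2), the cell cycle from 11.2 to 18.8% (32) and ribosomal proteins from 9.06 to 20.2% (119). For root against flower, MVA went from 37.5 to 14.3%, prenyltransferases from 14.3 to 0%, flavonoid genes from 32.3 to 0% (9), the fixed terpene synthase list from 26.7 to 50% (4), SF3 genes from 40 to 0% (1) and the cell wall from 36.5 to 83.3% (6). For root against fruit, MEP went from 10 to 0% (7), MVA from 6.25 to 0% and MADS genes from 42.9 to 0% (1). The other 16 were of lists not described for that comparison.

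The deviations of the replicates correlated between tissues at 0.436 for root and leaf, 0.384 for root and flower and 0.489 for leaf and flower, against -0.156, 0.101 and -0.0371 for fruit with root, leaf and flower, so that the replicate numbers are not shown to pair fruit with the other tissues. With the number as a block, the 6 comparisons gave 3300, 5354, 443, 5181, 2617 and 3840 calls and 1035, 2097, 2749 and 558 root-, leaf-, flower- and fruit-enriched genes, 126 of 142 named calls passed, and camera kept all 56 set tests. The 16 others were comp19097_c0 against leaf and HSP26.5 (comp18977_c0) against flower, and against fruit AGL12 (comp3886_c0), DEFA (comp20901_c0), GH3.5 (comp7449_c0), CYP71A1 (comp16766_c0), UGT85A3 (comp19699_c0), UGT74F1 (comp6591_c0), Os07g0190000 (comp20919_c0), comp15294_c0, VIT_19s0014g04930 (comp16860_c0) and LBD4 (comp13389_c0). For leaf against fruit they were OLE1 (comp23438_c0), MATP6-A (comp6808_c0) and HSD1 (comp7508_c0), and among fruit-enriched genes GY3 (comp17721_c0). With the fruit numbers crossed, 566 genes passed for root against fruit. ISPG (comp16115_c0), at 0.23 for root against leaf without the block, was at -0.045 with it.

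PAL (comp23045_c0), lower in root than in flower on counts, was at 0.21 on log2(TPM + 1), 0.21 with the pseudocount of 0.1, without a filter, with the stricter filter and without trend, and 0.22 with quantile normalization, but at -0.48 with median-ratio scaling, where it did not pass. Its effective length implied by counts and TPM was 2834 and 2758 bases in the flower libraries and 781 to 1051 in the others, which lowers its TPM in flower by construction. Length alone did not give the change of sign, since the median-ratio setting uses the same lengths.

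The other changes of direction were of results that did not pass. For root against leaf, ISPH (comp18951_c0) was at 0.0012 with DESeq2 size factors and the Wald test, 0.30 with total scaling, 0.092 on the TPM with either filter, none or no trend and 0.091 with the pseudocount. ISPE (comp17283_c0) was at 0.11 with total scaling, ISPG (comp16115_c0) at -0.23 with limma-trend on log2(CPM + 1), -0.0029 with quantile normalization and -0.24 with median-ratio scaling, and Os07g0190000 (comp22577_c0) at -0.14 with limma-trend on log2(CPM + 1) and -0.11 with median-ratio scaling. TPS11 (comp21713_c1) was at 1.42 on the TPM with either filter, none or no trend, 1.44 with the pseudocount, 1.32 with quantile normalization and 1.06 with median-ratio scaling. Its implied effective length was 1167 bases in leaf replicate 1 and 192 to 240.4 in root, which lowers its TPM in that leaf library by construction. For root against flower, ISPD (comp15693_c0) was at -0.036 with DESeq2 size factors, -0.037 with the Wald test, -0.034 with limma-trend on log2(CPM + 1), -0.063 without TAR1-A and -0.086 with quantile normalization. The reductase comp23063_c0 was at 0.35 with total scaling, 0.48 on the TPM with either filter, none or no trend, 0.49 with the pseudocount and 0.53 with quantile normalization. IPI2 (comp12361_c0) was at 0.055 on the TPM in those settings and with the pseudocount, and 0.097 with quantile normalization. For root against fruit, At5g27450 (comp22839_c0) was at -0.012 with DESeq2 size factors, -0.010 without a filter, -0.013 with the Wald test and -0.12 without TAR1-A, and TPS6 (comp21039_c0) at -0.033 without TAR1-A.

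With 1 library left out, the same comparisons gave these ranges, ending on both sides of 0. For root against leaf they were -1.29 to 0.61 for ISPH (comp18951_c0), -1.38 to 0.37 for ISPE (comp17283_c0), -1.45 to 0.92 for ISPG (comp16115_c0), -1.07 to 1.17 for ISPF (comp15871_c0), -1.98 to 1.60 for comp22577_c0, -2.40 to 2.30 for TPS11 (comp21713_c1), -0.50 to 1.53 for comp23063_c0, -0.039 to 1.60 for HMGS (comp17997_c0), -0.10 to 2.35 for At3g14510 (comp17723_c0) and -0.031 to 1.35 for TPS5 (comp22816_c0). For root against flower they were -0.44 to 0.38 for ISPD (comp15693_c0), -0.81 to 1.90 for DXR (comp22957_c0), -0.51 to 1.04 for HMGS and -0.087 to 0.62 for At5g47720 (comp19528_c0). For root against fruit they were -0.54 to 0.83 for At5g27450 (comp22839_c0), -0.13 to 2.11 for ISPF, -0.71 to 0.016 for IPI2 (comp12361_c0) and -0.19 to 0.40 for TPS6 (comp21039_c0).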
